A study of Mus musculus with 13 samples.

How the data were processed

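Single-cell RNA was profiled in 13 libraries of dissociated mouse kidney, in a study of orthotopic renal carcinoma; whether the NC kidneys carried a tumour is not stated. Per the labels, mice received an injection of the nucleoside analogue 4-thiouridine before tissue collection. Single cells were paired with barcoded beads on a microfluidic chip (Well-paired-seq), captured RNA was treated with iodoacetamide to convert the analogue, and libraries were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name STAR and the mm10 genome, without a version or a role for either. The deposited tables hold raw counts, whole numbers per gene and cell barcode, with no normalization. The labels do not say whether they count molecules or reads, or how barcodes were selected before deposit. New and old RNA are not separated in these tables, so the planned results on the share of new RNA were not run.

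Titles place the libraries in 7 title groups: NC with 2 libraries, D3 with 1, and D5, D7, D9, D11 and D20 with 2 each. The number after D was read as days, an assumption, since the labels spell out neither it nor NC. The barcode names of the D libraries carry what look like collection dates with the same spacing as the D numbers, so day and date cannot be told apart. The labels do not say that the 2 libraries of a title group came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical, and not the spread between animals. In the main gene fits of D against NC, each title group had its own coefficient. Their p-values rest on the spread within pairs of libraries, and the spread between time points does not enter them.

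Barcodes with at least 200 genes, at least 400 counts and under 50% mitochondrial counts were kept, and doublets called by Scrublet within each library were removed. Scrublet called 246 of the 59778 passing barcodes (0.412%), too few for doublets to be regarded as removed. Counts were scaled to 10000 per barcode and logged, and 2000 variable genes, 40 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 in scanpy 1.11.5 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Clusters were named from markers of 21 cell types. A name needed at least 3 markers, each detected in at least 10% of the cluster's barcodes and at a level at least 2 times the mean of the other clusters (10 CPM added to both). The type with the highest mean log2 ratio over its markers was taken, unless another type had more markers among the 10 leading genes. Of 31 clusters, 28 were named, in 13 classes. Clusters 10, 24 and 29 stayed unnamed and were counted in no class. The marker lists, 18 gene lists, comparisons, tests, thresholds and a first set of other settings were set before the data were examined.

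The share of barcodes per class, out of all barcodes of the library, was compared between D and NC libraries by an exact permutation test over all 78 assignments, two-sided. The shares of a library add up to a fixed total, so a rise in a class by itself lowers the others. Its trend over the 11 D libraries was tested by Pearson and Spearman correlation with log2 of the day and 100000 permutations, two-sided. Both were adjusted by Benjamini-Hochberg over the 13 classes. Intervals of single shares are 95% Wilson intervals. The limit for a count of 0, and the fold given against a group at 0, use 3 counts over the library or over the group. These intervals and limits cover counting error only.

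For each class, counts were summed per library with at least 20 barcodes of the class and fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling, filterByExpr and the quasi-likelihood test. D against NC was the mean of the coefficients of the D title groups minus NC, so that D3 weighs as much as a pair of libraries. The trend was the slope on log2 of the day, in log2 units per doubling of the day. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. D against NC was run in the proximal tubule, macrophage or monocyte, endothelial and T cell classes, and the trend in the carcinoma, macrophage or monocyte, proximal tubule and T cell classes. A gene with 0 counts in a whole title group can have no usable standard error and is then not called. This applied to 572 genes in the proximal tubule class, 503 in the macrophage class, 136 in the T cell class and 51 in the endothelial class. Gene lists with at least 5 tested genes were tested by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists.

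The genes named were fixed by rule for each class and comparison: the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 5, then up to 3 called members with the smallest p from each gene list. Pseudogenes and genes that may share reads with copies were passed over in the first part of the rule (1421 of 23937 genes, judged on 22990 with a transcript in GENCODE M21). Other genes named were chosen after their values were seen. Beside a gene, the ratio of its level in the class to its level over all barcodes of the same libraries, on the side where it is higher, shows whether the class holds more of it than the tissue as a whole.

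Each fit was tested on simulated data with 200 changed genes. In D against NC, 61% of genes changed by 1 on the log2 scale were called in the proximal tubule class, 60% in the endothelial class, 48% in the T cell class and 6% in the macrophage class. A slope of 0.5 was called for 59% of genes in the carcinoma class, 39% in the macrophage class, 18% in the proximal tubule class and 17% in the T cell class. Of the simulated calls, 2.08 to 11.63% were false. Simulated libraries were drawn independently, so libraries of a title group shared nothing and title groups had no spread of their own. False calls that such spread would bring to the real fits are not measured by this simulation.

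Other settings chosen at that point were RLE size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, at least 500 genes per barcode, doublets kept, clustering at resolution 2.0, no D3, a slope on the day itself, late against early time points, a replicate block, an estimated correlation in camera, and leaving out each library in turn. Settings added after seeing the data were a single coefficient for all D libraries, the same with the libraries of each title group summed, the libraries of each time point summed in the trend, the trend without both D20 or both D9 libraries, clusters 10 and 24 counted in the macrophage and proximal tubule classes, the mean of each time point as a single point in the share trends, and the limit to called genes at or above their level over all barcodes. Figures were drawn with matplotlib 3.10.9.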

Results

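Whole-transcriptome counts of single barcodes were available for 13 libraries of mouse kidney from an orthotopic renal carcinoma model: 2 NC libraries, 1 D3 library, and 2 libraries each for D5, D7, D9, D11 and D20. After filtering, 59532 barcodes with 154025550 counts over 23937 genes remained. The D9 replicate 1 library had the fewest total counts, 7626319 in 3617 barcodes, and the D9 replicate 2 library the most, 17017174 in 5839 barcodes. The NC libraries held 7713042 and 8396032 counts, with medians of 1469.5 and 1334.5 counts per barcode. The D20 libraries had the deepest barcodes, with medians of 3116 and 3263 counts. Median depth in the other D libraries ranged from 1520 counts in D9 replicate 1 to 2206 in D9 replicate 2.

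The first question was how the cell composition of the D libraries differed from that of the NC libraries. Barcodes of the carcinoma class, named from the keratins Krt8, Krt18 and Krt20 with Cdkn2a and Slpi, made up 32.3% ± 19.5 (SD, n = 11) of the D libraries and 0.0797% ± 0.04 (SD, n = 2) of the NC libraries. Macrophages or monocytes made up 35.8% ± 6.90 against 0.771% ± 0.144. Proximal tubule barcodes fell from 54.0% ± 0.0895 in NC to 15.2% ± 15.3 in D, endothelial barcodes from 11.5% ± 0.08 to 2.03% ± 2.20, and pericytes or smooth muscle from 1.46% ± 0.0453 to 0.289% ± 0.396. Each of these 5 differences had the same direction in 11 of 11 D libraries and an exact permutation p of 0.0256, the smallest the design allows. After adjustment over the 13 classes the p was 0.0667, so no class passed the threshold. With 0.0256 as the smallest p, passing needs more than 5 classes at that value. A single class could therefore not pass, however large its difference. The distal convoluted tubule class had an exact p of 0.0769 and the dendritic cell class 0.103. T cells (p = 0.615), neutrophils (p = 0.513), fibroblasts (p = 0.308), loop of Henle (p = 0.282), collecting duct principal cells (p = 0.538) and intercalated cells (p = 0.564) gave no detectable difference in the same exact test. An unnamed cluster marked by Cx3cr1, Ccl4 and Cd72, with C1qa, Csf1r and Adgre1 detected, held 8.91% and 9.46% of the NC barcodes and is not counted among the macrophages here.

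Over the 11 D libraries, the carcinoma share rose with the day and the tubule shares fell. Mean carcinoma shares were 2.29% at D3, 13.3% at D5, 21.7% at D7, 38.7% at D9, 43.0% at D11 and 59.9% at D20. Proximal tubule shares over the same time points went from 49.2% to 28.3%, 19.0%, 6.31%, 4.15% and 0.97%. Pearson's r with log2 of the day was 0.971 for carcinoma (permutation p = 1e-05, the smallest 100000 resamples give; adjusted p = 4.33e-05; Spearman's rho 0.952, p = 5e-05; r = 0.945 without the D20 pair). For the proximal tubule, r was -0.929 (permutation p = 1e-05, adjusted p = 4.33e-05; rho -0.989, p = 1e-05; r = -0.991 without the D20 pair). Over the means of the 6 time points, where pairs of libraries count once, r was 0.987 for carcinoma and -0.943 for the proximal tubule, each with an exact p of 0.00139.

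The other nephron and vessel classes also fell with the day in the permutation test: distal convoluted tubule (r = -0.880, adjusted p = 4.33e-05, rho -0.917), loop of Henle (r = -0.844, adjusted p = 0.000364, rho -0.805), endothelial (r = -0.832, adjusted p = 0.000715, rho -0.887), pericytes or smooth muscle (r = -0.829, adjusted p = 6.5e-05, rho -0.899) and intercalated cells (r = -0.825, adjusted p = 0.00149, rho -0.847). Without the D20 pair, r for these 5 classes lay between -0.938 and -0.863. These tests count the libraries of a time point as separate. Over the means of the 6 time points the exact permutation p, unadjusted, was 0.00556, 0.00694, 0.0153, 0.00139 and 0.0139 in the same order. For macrophages r was 0.596 there (exact permutation p = 0.208). Endothelial barcodes were 5.08% of D3 and 0.188% of D20. The macrophage share of all barcodes gave no detectable trend over all D libraries (r = 0.473, permutation p = 0.144), but without the D20 pair r was 0.848 with a permutation p of 0.0037. Mean macrophage shares were 24.6% at D3 and 34.2% at D20, while carcinoma went from 2.29% to 59.9% and so lowered the other shares. Shares among barcodes outside the carcinoma class were not tested. A macrophage trend among those barcodes is therefore not excluded. How much of the falls in other classes comes from the carcinoma rise was not tested. T cells (r = -0.582, adjusted p = 0.0901) and dendritic cells (r = -0.611, adjusted p = 0.0746) did not pass on log2 of the day. They passed by Spearman's rho (both -0.704, adjusted p = 0.028). Without the D20 pair r was -0.172 and -0.209, so that relation rests on D20. Neutrophils (r = 0.0474), fibroblasts (r = -0.180) and collecting duct principal cells (r = -0.133) gave no trend by r. For collecting duct principal cells rho was -0.636 (adjusted p = 0.0509), with a single high share of 5.34% in D11 replicate 2. Day is confounded with collection date, as far as the barcode names show, and no time point holds more than a single date.

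**Figure D1:**
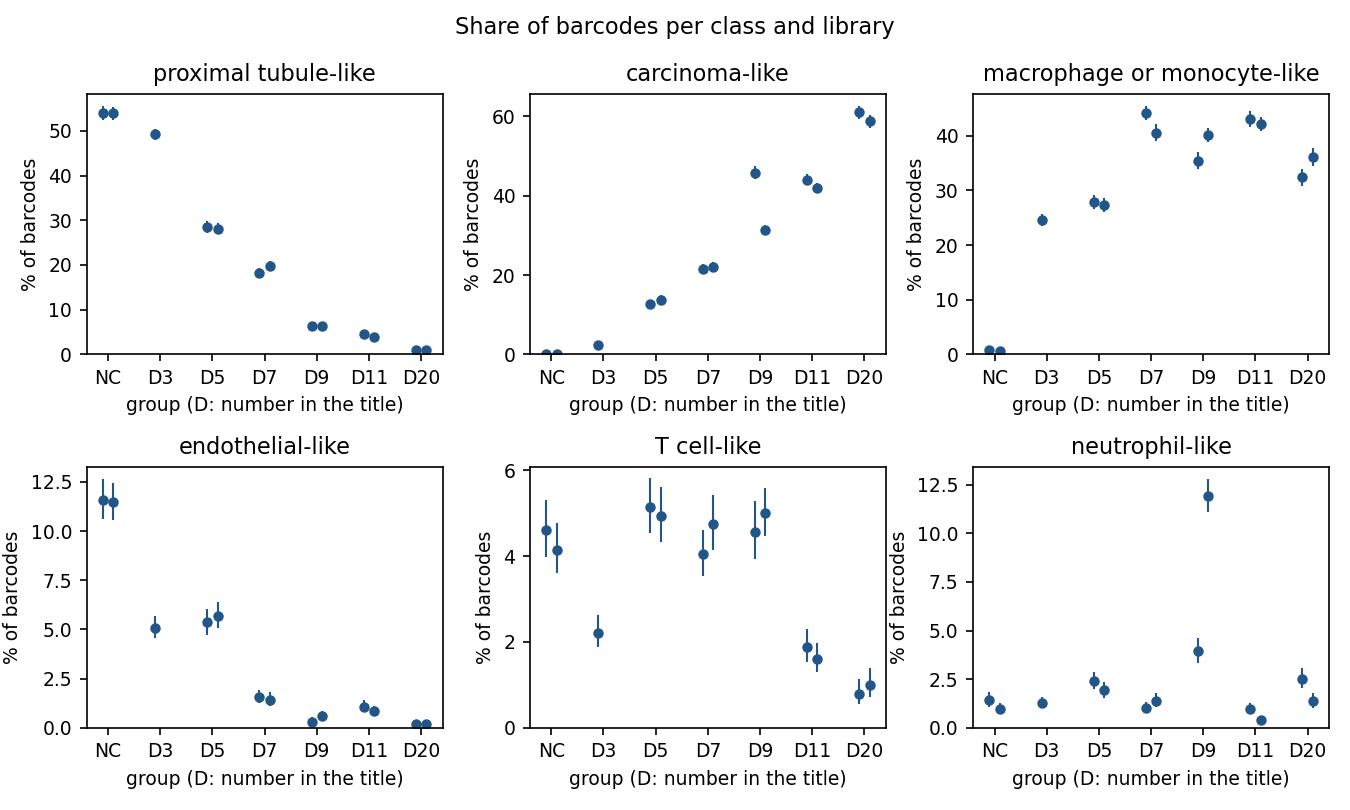
Share of barcodes (percent, vertical axis) in 6 classes against title group (horizontal axis). Each point is a library and each vertical bar its 95% Wilson interval; carcinoma means go from 2.29% at D3 to 59.9% at D20 while proximal tubule means go from 49.2% to 0.97%.

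Genes that mark the sex of an animal parted the D libraries from the NC libraries. Xist, the long noncoding RNA of the inactive X chromosome (mm10 chromosome X, 103460366 to 103483254), stood at 1142 and 1193 CPM over all barcodes of the NC libraries and at no more than 0.524 CPM in any D library. Counts of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d summed to 0 in both NC libraries and to between 99.5 and 337 CPM in the D libraries. The labels call the mice female. In proximal tubule barcodes the Y-linked genes lay between 215 and 364 CPM in every D library, and in macrophages between 201 and 352 CPM. Carcinoma barcodes held little of either, with Y-linked levels of 2.66 to 40.6 CPM and Xist at no more than 0.408 CPM. Every comparison of D with NC in the following paragraphs therefore also compares barcodes that differ in Xist and Y-linked RNA.

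**Figure D2:**
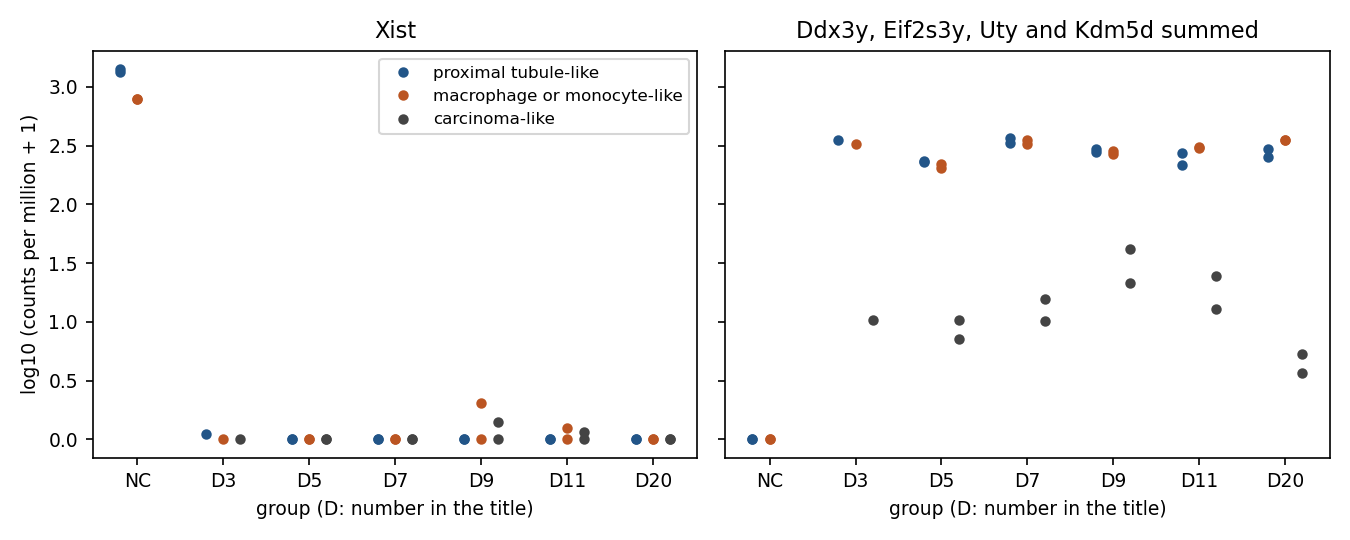
Level of Xist and summed level of Ddx3y, Eif2s3y, Uty and Kdm5d (log10 of CPM + 1, vertical axes) per library in proximal tubule, macrophage and carcinoma barcodes, by title group. Each point is a library; in proximal tubule barcodes Xist is at 1339 and 1413 CPM in NC and at most 0.111 CPM in D, while Y-linked genes are at 0 in NC and at 215 to 364 CPM in D.

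In proximal tubule barcodes, the comparison of D with NC asks how tubule cells in the D kidneys differ from those in the NC kidneys. Ugt8a, a ceramide galactosyltransferase (chromosome 3, 125865271 to 125938619), had 1 count over both NC libraries and a mean of 213 CPM ± 58.0 (SD, n = 11) in D, a pooled ratio of 2413 with a 95% counting interval of 433 to 95343. Slc7a13, an amino acid transporter of the straight proximal tubule (chromosome 4, 19818725 to 19842218), rose from 3.17 CPM ± 0.58 (SD, n = 2) to 773 ± 501, a log2 change of 7.47 ± 0.26 (SE; adjusted p = 4.16e-50, edgeR). Kap, the kidney androgen-regulated protein (chromosome 6, 133849851 to 133853762), rose from 2039 CPM ± 5.6 to 18719.9 ± 10925 (log2 2.75 ± 0.10, adjusted p = 4.06e-47). All 3 were higher in 11 of 11 D libraries. The rise of Kap was much smaller with the unnamed cluster 24, almost absent from D, counted as proximal tubule (given below). Bhmt, which remethylates homocysteine, fell by 4.95 ± 0.25 on the log2 scale, and Gatm, the first enzyme of creatine synthesis, by 4.20 ± 0.18, both lower in 11 of 11 D libraries (adjusted p = 4.72e-35 and 6.04e-41).

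**Figure D3:**
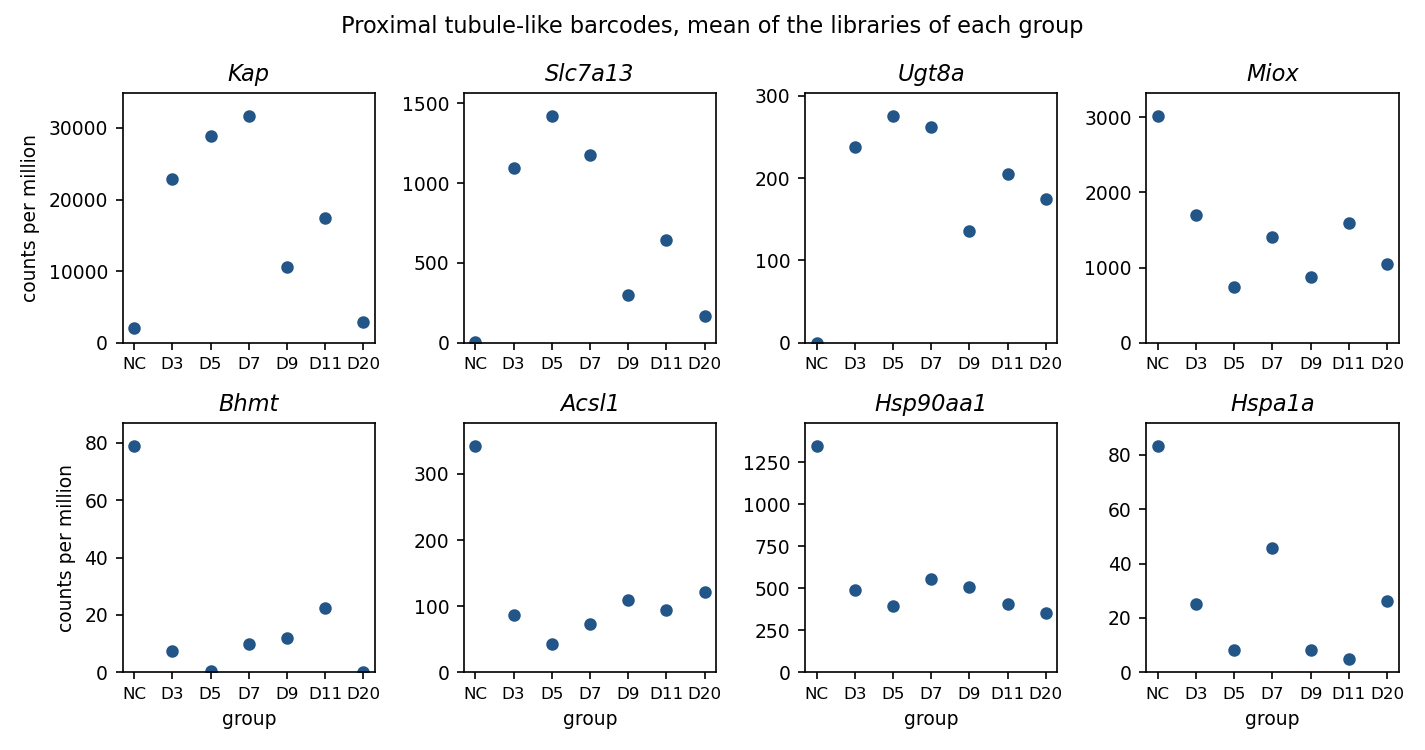
Mean level (CPM, vertical axis) of Kap, Slc7a13, Ugt8a, Miox, Bhmt, Acsl1, Hsp90aa1 and Hspa1a in proximal tubule barcodes by title group (horizontal axis), each group the mean of its libraries. Slc7a13 goes from 3.17 CPM in NC to 1094 at D3 and 168 at D20, and Hsp90aa1 is lower in 11 of 11 D libraries than in NC.

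Heat shock chaperones fell as a group in the tubule: 12 of 12 tested members were lower in D (12 when adjusted over the list alone; camera adjusted p = 5.6e-13, and adjusted p = 0.00327 with an estimated correlation). Hsp90aa1 fell by 1.71 ± 0.08 on the log2 scale and Hsph1 by 1.54 ± 0.10. Fatty acid oxidation had 10 members lower and 1 higher of 19 (2 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.000349, but adjusted p = 0.0827 with an estimated correlation). Acsl1, which activates long-chain fatty acids, fell by 2.17 ± 0.10 and Acaa2, a thiolase of mitochondrial oxidation, by 1.56 ± 0.09 (lower in 11 of 11 and 9 of 11 D libraries). Of the 15 immediate early and dissociation genes, 8 were lower and 2 higher (camera adjusted p = 0.0136, adjusted p = 0.319 with an estimated correlation), with Jun at -1.21 ± 0.08 and Klf6 at -2.06 ± 0.11. Proximal tubule transport and identity genes went both ways, 6 higher and 10 lower of 18 (camera adjusted p = 0.232), and Miox, which degrades inositol, fell by 1.49 ± 0.08. The NC and D barcodes of this class lay partly in different clusters. Cluster 7 held 30.7% and 31.6% of the NC barcodes and at most 0.185% of any D library, while cluster 3 held 25.3% of D3 and at most 0.022% of NC. Cluster 5 was shared, with 15.2% and 14.9% of the NC barcodes, 13.3% of D3 and at most 5.48% of the other D libraries.

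Some interferon, antigen presentation, matrix, cell cycle and macrophage genes, such as Isg15, H2-D1, Fn1, Mki67 and Ccl8, were higher in the same tubule barcodes. Interferon response genes had 8 higher and 0 lower of 19 (camera adjusted p = 6.45e-08, adjusted p = 0.0342 with an estimated correlation), with Isg15 at 3.10 ± 0.42. MHC class I presentation had 7 higher of 13 (camera adjusted p = 4.56e-06, adjusted p = 0.0507 with an estimated correlation), with H2-D1 at 1.50 ± 0.11. MHC class II had 6 higher of 8 (7 adjusted over the list alone; adjusted p = 5.02e-06) and NF-kB and cytokine genes 3 higher of 15 (adjusted p = 3.61e-06), neither passing with an estimated correlation (adjusted p = 0.0745 and 0.0671). Extracellular matrix and fibrosis genes had 5 higher of 13 (adjusted p = 2.8e-06, adjusted p = 0.0289 with an estimated correlation), with Fn1, fibronectin, at 4.20 ± 0.41. Cell cycle genes had 7 higher and 2 lower of 20 (9 and 2 adjusted over the list alone; adjusted p = 8.12e-05, adjusted p = 0.0289 with an estimated correlation), with Mki67 at 2.04 ± 0.30. Tumour-associated macrophage genes had 9 higher and 2 lower of 17 (adjusted p = 2.8e-06, adjusted p = 0.0289 with an estimated correlation). The examples were low here for the tissue: the level in tubule barcodes was 0.13 times that over all barcodes for Isg15, 0.221 times for H2-D1, 0.167 times for Fn1 and 0.136 times for Mki67. The macrophage genes Arg1 and Ccl8, at 0 counts in NC tubule barcodes, were at least 224-fold and 449-fold higher in D, at 0.105 and 0.134 times their level over all barcodes. Leaving out D20 replicate 2 ended the call on Arg1 (adjusted p = 1 against 5.24e-14).

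In all, edgeR called 1076 genes higher and 2454 lower in D of 11669 tested in the proximal tubule class, of which 350 and 1563 were at or above their level over all barcodes. RLE size factors put 42.9% of 3108 called genes higher and the DESeq2 Wald test 57.4% of 3094, against 30.5% with TMM. The median log2 change over all tested genes was -0.195 with TMM, -0.0874 with RLE and 0.0066 with DESeq2. A single coefficient for all D libraries called 1056 genes. There Acaa2 (-1.18), Jun (-1.05) and Klf6 (-1.47) lost the call and Gatm was at -2.34. With the libraries of each title group also summed 45 genes were called, where Ugt8a, Acsl1, Hsp90aa1 and Arg1 kept it and the other genes named here for the tubule comparison did not. With the unnamed cluster 24, which holds 7.14% and 7.34% of NC barcodes, counted as proximal tubule, the change of Kap was 0.41 and that of Fn1 2.34.

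In macrophages or monocytes, the single genes Arg1, Ccl8, Hmox1, Spp1 and Plin2 were higher in D than in NC, and Retnla and genes of MHC class II were lower. Arg1, arginase (chromosome 10, 24915221 to 24927484), and Ccl8, a monocyte chemokine, had 0 counts in NC and means of 1898 CPM ± 957 and 2668 ± 1455 (SD, n = 11) in D, at least 71.3-fold and 100.3-fold higher. Hmox1, which degrades haem, rose by a log2 of 3.12 ± 0.22 (adjusted p = 2.3e-08), Spp1, osteopontin, by 2.45 ± 0.15 (adjusted p = 5.93e-09) and Plin2, a lipid droplet coat protein, by 1.80 ± 0.17 (adjusted p = 1.43e-06, edgeR). Retnla, a secreted resistin-like protein (chromosome 16, 48842551 to 48844461), fell by 5.89 ± 0.19 (adjusted p = 9.87e-13), from 4697 CPM ± 1721 (SD, n = 2) to 63.5 ± 37.6. Each of these genes had the same direction in 11 of 11 D libraries. The NC and D barcodes of this class were spread differently over the clusters. Cluster 2, with Lyz1, Ccr2 and Chil3 among its leading genes, held 0.719% and 0.454% of the NC barcodes, out of 0.873% and 0.67% for the class. It was shared with the D libraries, where it held 3.30 to 22.7% of the barcodes. Cluster 1, with Cd163, Ccl8 and Mrc1, held 0 of NC replicate 1 (which allows a share of up to 0.077%), 0.043% of NC replicate 2 and 6.94 to 18.4% of the D libraries. A different mix of monocytes and macrophages and a change within either are not separated here.

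Of the 8 MHC class II presentation genes, 7 were lower (camera adjusted p = 6.18e-10, adjusted p = 0.0744 with an estimated correlation), with H2-Aa at -2.61 ± 0.10, H2-Eb1 at -2.92 ± 0.08 and the invariant chain Cd74 at -1.87 ± 0.07. Tumour-associated macrophage genes had 12 higher and 0 lower of 18 (13 adjusted over the list alone; adjusted p = 3.4e-12, adjusted p = 0.0348 with an estimated correlation). With the unnamed cluster 10 counted as macrophages that list had 13 higher and 4 lower (adjusted p = 2.25e-05), and it no longer passed with an estimated correlation (adjusted p = 0.0637). Cell cycle genes had 5 higher of 20 (6 adjusted over the list alone; adjusted p = 7.7e-05, adjusted p = 0.109 with an estimated correlation) and tubular injury genes 5 higher of 15 (adjusted p = 0.00024, adjusted p = 0.0744 with an estimated correlation). With cluster 10 counted these lists had 18 higher and 0 lower, and 11 higher and 2 lower, and both passed with an estimated correlation (adjusted p = 0.0353 and 0.0473). Antioxidant, mitochondrially encoded and proximal tubule genes passed in the smaller class (adjusted p = 0.0257, 0.00707 and 0.00995) but not with an estimated correlation (adjusted p = 0.185, 0.451 and 0.652). NF-kB and cytokine genes showed no shift as a list, with 2 higher and 3 lower of 15 (2 and 4 adjusted over the list alone; adjusted p = 0.826). Glycolysis and hypoxia genes had 9 higher of 21 (11 adjusted over the list alone; adjusted p = 6.44e-09, adjusted p = 0.0744 with an estimated correlation), with Pkm, pyruvate kinase, at 2.04 ± 0.14 and Tpi1 at 2.26 ± 0.17. Immediate early and dissociation genes had 6 lower and 1 higher of 15 (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.00446, adjusted p = 0.451 with an estimated correlation), with Atf3 at -2.10 ± 0.15. The cytokine Il1b fell by 2.02 ± 0.12 on the log2 scale, while the chemokine Ccl7 rose by 3.79 ± 0.38.

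The NC side of this comparison rests on 34 and 31 barcodes. edgeR called 602 genes higher and 197 lower of 12774 (2297 at an unadjusted p under 0.05), with 333 called without NC replicate 1 and 340 without NC replicate 2. The median change over all genes was 0.60 with TMM, 0.44 with RLE and 0.0079 with DESeq2. The share of called genes that were higher was 75.3%, 59.0% and 34.2% in turn. With a single coefficient for all D libraries 368 genes were called. Hmox1 (3.75), Cd74 (-1.58), Il1b (-1.75) and Ccl7 (4.24) then lost the call. With title groups also summed 6 genes were called, Retnla among them and none of the others named here. With the unnamed cluster 10 counted as macrophages, which brings NC to 381 and 469 barcodes, 2702 genes were higher and 2223 lower. Ccl8 was then at 7.46, Spp1 at 2.70, Hmox1 at 2.29, H2-Aa at -2.74 and Retnla at -3.12. C1qb, a complement gene called higher in the smaller class (2.18 ± 0.14), was at -0.59.

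Endothelial barcodes could be compared in 8 D libraries, since the D20 libraries and D9 replicate 1 held fewer than 20. The single genes Kdr (chromosome 5, 75932827 to 75978458) and Flt1, receptors of vascular endothelial growth factor, and the co-receptor Nrp1 changed by -1.18 ± 0.13, -0.76 ± 0.13 and -1.76 ± 0.15 on the log2 scale (adjusted p = 6.44e-11, 3.54e-06 and 7.67e-15, edgeR). The cell cycle inhibitor Cdkn1a fell by 1.46 ± 0.13 and the inducible chaperones changed by -3.63 ± 0.26 (Hspa1a) and -3.36 ± 0.32 (Hspa1b). Sparc, a matrix glycoprotein (chromosome 11, 55394500 to 55423183), rose by 1.25 ± 0.16 (adjusted p = 5.77e-09), from 2537 CPM ± 107 (SD, n = 2) to 7222 ± 3642 (SD, n = 8). All 7 genes had the same direction in 8 of 8 D libraries, and their levels were 2.59 to 17.5 times those over all barcodes.

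Tumour endothelium and angiogenesis genes went both ways, with 3 higher and 5 lower of 12 (camera adjusted p = 0.0707), and so did heat shock genes, with 2 higher and 3 lower of 12 (adjusted p = 0.153). Cell cycle genes had 13 higher of 17 (adjusted p = 6.95e-08, adjusted p = 0.172 with an estimated correlation), with Mcm6, a replication helicase subunit, at 3.50 ± 0.43. Glycolysis and hypoxia genes had 8 higher and 1 lower of 14 (9 and 1 adjusted over the list alone; adjusted p = 1.53e-05, adjusted p = 0.169 with an estimated correlation), with Pkm at 1.37 ± 0.16. The tubular injury list had 9 higher and 1 lower of 14 (adjusted p = 8.45e-07, adjusted p = 0.169 with an estimated correlation), with Plin2 at 2.48 ± 0.23. Tumour-associated macrophage genes had 11 higher of 15 (adjusted p = 1.08e-11, adjusted p = 0.111 with an estimated correlation). MHC class II genes had 5 higher of 6 (6 adjusted over the list alone; adjusted p = 3.41e-06, adjusted p = 0.169 with an estimated correlation). Proximal tubule genes had 7 lower of 12 (2 higher and 7 lower adjusted over the list alone; adjusted p = 0.0276, adjusted p = 0.4 with an estimated correlation), with Lrp2 at -2.90 ± 0.37. Among these, the level in endothelial barcodes was 0.699 times that over all barcodes for Mcm6, 0.768 times for Pkm, 0.585 times for Plin2, 0.114 times for Lrp2, and 0.266 times for the macrophage gene C1qb, which rose by 3.58 ± 0.33.

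edgeR called 685 genes higher and 999 lower of 5790 in the endothelial class (817 in all without NC replicate 1 and 780 without NC replicate 2), of which 130 and 898 were at or above their level over all barcodes. The DESeq2 Wald test called 558, 62.2% of them higher against 40.7% with edgeR. A single coefficient for all D libraries called 269, where Kdr (-1.04), Flt1 (-0.74), Sparc (1.51) and Lrp2 (-1.46) lost the call. Title groups summed gave 16, where Hspa1b and C1qb kept it and the other genes named here did not.

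In barcodes of the T cell class, Tnfrsf9, Mki67 and Birc5 were higher in D than in NC, and Ccl5, Ifng, Fosb and Btg2 were lower. The class also holds natural killer cells: Gzma, Nkg7 and Il2rb are among its leading genes, and at resolution 2.0 a natural killer cluster of 542 barcodes forms. Tnfrsf9, the costimulatory receptor 4-1BB (chromosome 4, 150914562 to 150946102), rose by 2.24 ± 0.38 on the log2 scale (adjusted p = 8.48e-05, higher in 10 of 11 D libraries, edgeR). Mki67 rose by 1.70 ± 0.31 and Birc5, a mitotic survivin, by 2.71 ± 0.35 (adjusted p = 0.000232 and 1.3e-06, 11 of 11), with 2.76 and 4.14 when NC replicate 1 was left out. Ccl5, a chemokine of cytotoxic cells (chromosome 11, 83525778 to 83530518), fell by 1.23 ± 0.19 (adjusted p = 2.29e-05, lower in 11 of 11) and Ifng, interferon gamma, by 2.95 ± 0.60 (adjusted p = 0.000783, lower in 10 of 11). The Ifng call was lost without NC replicate 2 (-2.37). Fosb fell by 2.59 ± 0.21 and the antiproliferative gene Btg2 by 1.80 ± 0.17 (adjusted p = 6.53e-10 and 1.24e-08).

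Cell cycle genes had 10 higher of 20 in T cells (13 adjusted over the list alone; camera adjusted p = 4.61e-08, adjusted p = 0.105 with an estimated correlation), and their examples were at 1.58 (Birc5) and 2.14 (Mki67) times the level over all barcodes. T cell exhaustion genes had 2 higher of 9, Tnfrsf9 and Havcr2 (camera adjusted p = 0.154; Havcr2 not called without NC replicate 1, adjusted p = 0.0517 against 0.00525), and cytotoxic effectors 3 lower of 9 (adjusted p = 0.219). Among natural killer markers, Gzma (0.03, adjusted p = 0.963) and Ncr1 (-0.67, adjusted p = 0.431) were not called, so a part of natural killer cells in the lower Ccl5 and Ifng is left open. Immediate early and dissociation genes had 7 lower and 1 higher of 14 (2 higher and 7 lower adjusted over the list alone; adjusted p = 0.000121, adjusted p = 0.204 with an estimated correlation). Glycolysis genes had 8 higher of 14 (adjusted p = 7.96e-05, adjusted p = 0.204 with an estimated correlation), with Pkm at 1.62 ± 0.19, 0.908 times the level over all barcodes. Proximal tubule genes had 13 lower of 17 (adjusted p = 2.04e-10, adjusted p = 0.0643 with an estimated correlation). Tumour-associated macrophage genes had 13 higher of 16 (adjusted p = 1.17e-08, adjusted p = 0.0502 with an estimated correlation). The examples Miox (-2.99 ± 0.24) and Spp1 (2.10 ± 0.23) were at 0.274 and 0.394 times their level over all barcodes. The NC libraries also held mast cell genes in this class: Mcpt4, at 0 counts in D, was at least 176-fold lower there, and the change of Cma1 went from -7.22 to -0.66, no longer called, without NC replicate 2.

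edgeR called 627 genes higher and 899 lower of 6749 in T cells (839 without NC replicate 1, 710 without NC replicate 2), of which 219 and 639 were at or above their level over all barcodes. The DESeq2 Wald test called 782, with Ifng (-2.58) and Mcpt4 (adjusted p = 0.217) not called. A single coefficient called 647, with Ccl5 (-1.10) and Ifng (-1.88) not called. Title groups summed gave 20, which ended the call on every T cell gene named above except Mcpt4 and Cma1.

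The trend over the D libraries in carcinoma barcodes asks how tumour cells changed as tumours grew. Gpnmb, a transmembrane glycoprotein (chromosome 6, 49036546 to 49070929), rose by 1.19 ± 0.09 per doubling of the day (adjusted p = 2.94e-05, edgeR), from 71.7 CPM at D3 to 703 at D20. Acpp, an acid phosphatase (chromosome 9, 104288251 to 104337748), rose by 1.23 ± 0.10, Mme, the peptidase neprilysin, by 1.54 ± 0.16 and Selenop, a selenium carrier, by 1.15 ± 0.11 (adjusted p = 2.94e-05, 0.000228 and 0.000156). Ndrg1, a gene induced by hypoxia, rose by 0.43 ± 0.07 (adjusted p = 0.00279). Ccdc80, a secreted matrix protein (chromosome 16, 45093402 to 45128077), fell by 0.98 ± 0.08 per doubling and the scaffold protein Akap12 by 0.85 ± 0.12 (adjusted p = 4.13e-05 and 0.00175), with Ccdc80 going from 91.9 CPM at D3 to 17.5 at D20. Carcinoma barcodes of the time points were spread differently over the clusters. Cluster 6, with Gpnmb among its leading genes, held 23.1% and 24.04% of the D20 libraries, 0.235% of D3 and at most 5.58% of the others. Cluster 0 was shared, with 11.2% and 10.8% of the D7 libraries, 27.0% and 29.1% of D11 and 21.1% and 19.5% of D20.

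Cell cycle genes fell with the day: 8 of 20 were lower (12 adjusted over the list alone) and 0 higher, with a camera adjusted p of 3.23e-07, but adjusted p = 0.534 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, fell by 0.56 ± 0.07 per doubling, Top2a, topoisomerase 2 alpha, by 0.56 ± 0.08 and Mcm5 by 0.44 ± 0.07. Heat shock genes had 4 lower of 12 (5 adjusted over the list alone; adjusted p = 0.00592, adjusted p = 0.571 with an estimated correlation), with the mitochondrial chaperonin Hspd1 at -0.38 ± 0.07. Interferon response genes had 2 lower of 19 (3 adjusted over the list alone; adjusted p = 0.00592, adjusted p = 0.648 with an estimated correlation), Ifitm3 (-0.47 ± 0.12) and Ifi44 (-0.98 ± 0.25). Each of these calls was lost without D5 replicate 1 (-0.41 and -0.93), D5 replicate 2 (-0.43 and -0.98), D20 replicate 1 (-0.46 and -0.91) or D20 replicate 2 (-0.51 and -0.91). Proximal tubule genes had 5 lower of 16 (13 adjusted over the list alone; adjusted p = 2.27e-08, adjusted p = 0.534 with an estimated correlation), and Slc22a6, an organic anion transporter with a slope of -1.99 ± 0.39, stood at 0.032 times its level over all barcodes. The examples of the other groups were at or above that level except Ifi44, at 0.997 times.

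**Figure D4:**
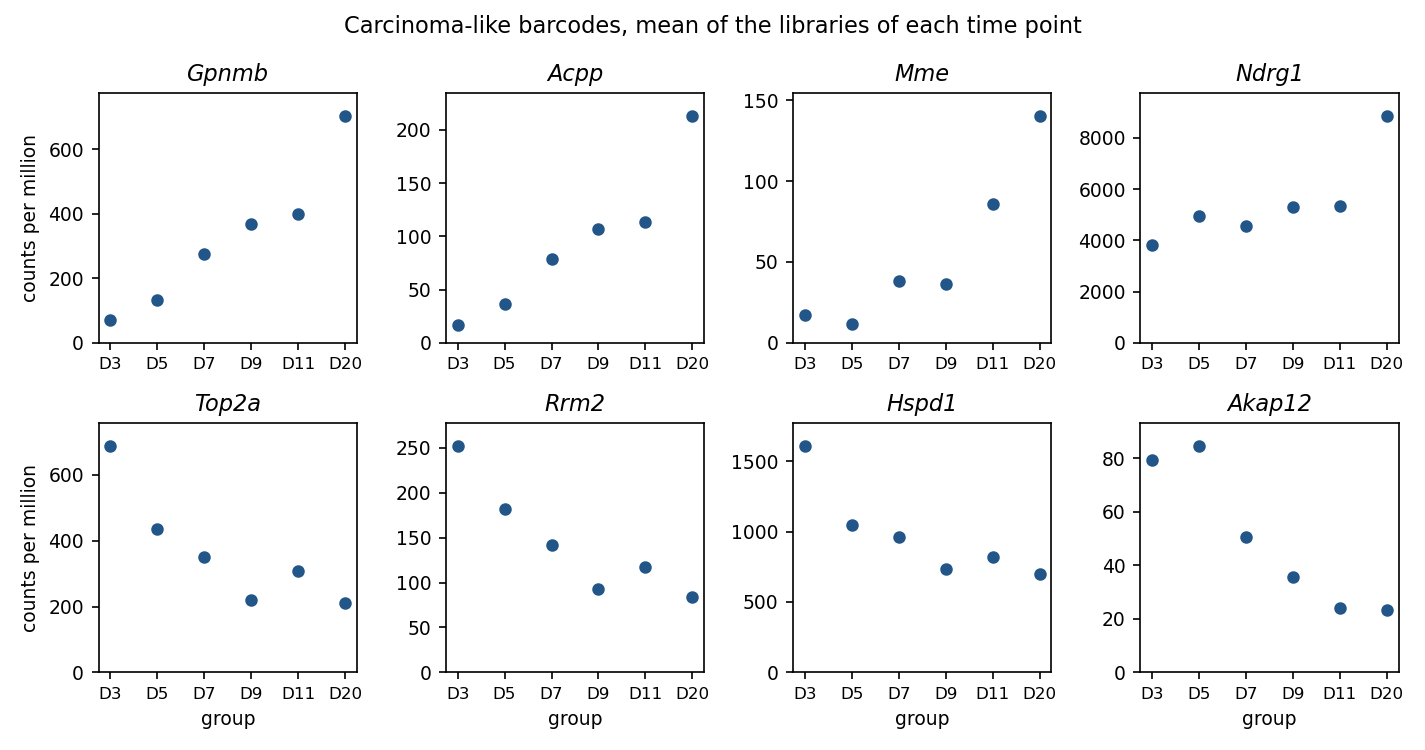
Mean level (CPM, vertical axis) of Gpnmb, Acpp, Mme, Ndrg1, Top2a, Rrm2, Hspd1 and Akap12 in carcinoma barcodes at D3, D5, D7, D9, D11 and D20 (horizontal axis), each the mean of the libraries of the time point. Gpnmb goes from 71.7 to 703 CPM and Top2a from 689 to 212.

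edgeR called 584 genes rising and 444 falling of 12271 in carcinoma barcodes, and the count was 440 without D20 replicate 2, 537 without D20 replicate 1, 607 without D5 replicate 1 and 609 without D3. With the libraries of each time point summed 17 genes were called, and of those named here Gpnmb, Acpp, Selenop and Ccdc80 kept the call. Without both D20 libraries the slope of Ndrg1 was 0.24 and not called.

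In macrophages over the same days, Lyz1, a lysozyme (chromosome 10, 117287797 to 117292868), rose by 1.85 ± 0.27 per doubling of the day (adjusted p = 0.00371, edgeR), from 58.0 CPM at D3 to 971 at D20. Ctsk, the protease cathepsin K, rose by 2.02 ± 0.22, the tetraspanin Cd9 by 0.76 ± 0.12 and Fdps, an enzyme of cholesterol synthesis, by 1.26 ± 0.14 (adjusted p = 0.00101, 0.00616 and 0.00106). Il10, an anti-inflammatory cytokine (chromosome 1, 131019845 to 131024974), fell by 1.73 ± 0.22, the scavenger receptor Cd36 by 1.24 ± 0.20, the chemokine Cxcl1 by 0.86 ± 0.15 and the interferon-induced gene Ifi44l by 0.91 ± 0.17 (adjusted p = 0.0019, 0.00668, 0.0077 and 0.0101). Lyz1, Cd9, Il10, Cxcl1 and Ifi44l were at or above their level over all barcodes, Cd36 at 0.911 times, Ctsk at 0.867 times and Fdps at 0.207 times. Macrophage barcodes of the time points were spread differently over the clusters. Cluster 1 was shared, with 12.1% of D3, 18.4% and 16.1% of the D7 libraries and 10.6% and 12.5% of the D20 libraries. Cluster 2, with Lyz1 its first leading gene, went from 5.30% of D3 to 22.6% and 22.7% of the D11 libraries and 8.02% and 9.03% of the D20 libraries, cluster 12, with Arg1 and Mmp12, from 0.286% of D3 to 8.53% and 8.82% of D20, and cluster 13, with Folr2 and Lyve1, from 4.89% of D3 to 6.34% and 6.94% of D7 and 1.79% and 1.72% of D20.

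Interferon response genes fell in macrophages, 6 of 20 (10 adjusted over the list alone; camera adjusted p = 2.33e-08, adjusted p = 0.337 with an estimated correlation), with Ifitm3 at -0.44 ± 0.09, a call lost without D3 (-0.40). MHC class I genes had 2 lower of 13 (adjusted p = 0.000193), NF-kB and cytokine genes 1 lower of 15 (adjusted p = 0.000844), cell cycle genes 2 lower of 20 (adjusted p = 0.000844) and immediate early genes 2 lower of 15 (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.00077), each with adjusted p = 0.337 with an estimated correlation. Tumour-associated macrophage genes showed no shift as a list (2 higher and 1 lower of 18, adjusted p = 0.898). Proximal tubule genes had 6 lower of 17 (14 adjusted over the list alone; adjusted p = 4.07e-14, adjusted p = 0.337 with an estimated correlation), and Lrp2, with a slope of -1.53 ± 0.27, was at 0.064 times its level over all barcodes.

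edgeR called 287 genes rising and 266 falling of 11720 in macrophages. The count was 264 without D20 replicate 1, 304 without D5 replicate 2, 318 without D20 replicate 2, 321 without D5 replicate 1, 351 without D3, 1761 without both D20 libraries and 1077 by the DESeq2 Wald test. With the libraries of each time point summed 3 genes were called and every macrophage slope named above lost its call, and Ctsk was at 0.94 without both D20 libraries.

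In proximal tubule barcodes over the days, Angptl7, a secreted angiopoietin-like protein (chromosome 4, 148495183 to 148500460), fell by 1.87 ± 0.29 per doubling of the day (adjusted p = 0.00866, edgeR), from 746 CPM at D3 to 60.8 at D20. Zbtb16, a zinc finger transcription factor, fell by 1.29 ± 0.20 and Acsm3, an acyl-CoA synthetase, by 1.33 ± 0.22 (adjusted p = 0.00866 and 0.0111). Apoe, apolipoprotein E (chromosome 7, 19696109 to 19699188), rose by 0.99 ± 0.13 (adjusted p = 0.0059), from 408 CPM at D3 to 2203 at D20, at 0.86 times its level over all barcodes. Gsta2, a glutathione transferase whose reads may be shared with near copies, rose by 1.35 ± 0.19 (adjusted p = 0.0059) and was at 38.5 times that level. Kap fell by 1.33 ± 0.30 per doubling (adjusted p = 0.0253), a call lost without D5 replicate 1 (-1.34), D5 replicate 2 (-1.34), D20 replicate 1 (-1.02) or D20 replicate 2 (-1.09). Tubule barcodes of the time points were also spread differently over the clusters. Cluster 3 held 25.3% of all D3 barcodes, of 49.2% for the class, but 0.525% of D9 replicate 1, of 6.39%, where cluster 14 held 4.87%, and 0.142% and 0.118% of the D20 libraries, of 1.02% and 0.918%. Cluster 5 was shared, with 13.3% of D3 and 0.397% and 0.296% of the D20 libraries.

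Cell cycle genes had 3 rising of 14 in tubule barcodes (11 rising and 1 falling adjusted over the list alone; camera adjusted p = 7.44e-06, adjusted p = 0.105 with an estimated correlation). Tumour-associated macrophage genes had 3 rising of 13 (5 adjusted over the list alone; adjusted p = 7.44e-06, adjusted p = 0.105 with an estimated correlation). Tubular injury genes had 4 rising of 14 (5 adjusted over the list alone; adjusted p = 5.77e-05, adjusted p = 0.272 with an estimated correlation). Krt20, a keratin of injured tubules and of the carcinoma class, rose by 1.74 ± 0.38 and was at 0.215 times its level over all barcodes. Proximal tubule transport and identity genes had 4 falling of 18 (6 adjusted over the list alone; camera adjusted p = 0.0568).

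The D20 libraries held 36 and 31 tubule barcodes. edgeR called 202 genes rising and 142 falling of 7436, of which 7 and 117 were at or above their level over all barcodes. The count was 87 without D5 replicate 2, 94 without D5 replicate 1, 181 without D11 replicate 1, 181 without D11 replicate 2, 195 without D3, 629 without D20 replicate 1, 600 without D20 replicate 2 and 1137 without both. With the libraries of each time point summed edgeR called 0 genes, against 344 (1575 at an unadjusted p under 0.05) with single libraries and 654 by the DESeq2 Wald test. The slope on the day itself gave 123, with Krt20 not called. The excess of rising genes depended on the setting. With the replicate block and D3 left out 21 genes were rising and 66 falling, and with no filter on low counts 439 and 437. RLE size factors (214 and 102) and the DESeq2 Wald test (413 and 241) kept the excess.

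In T cell barcodes, Calca and genes of the tubule were among those that fell over the days. Calca, the gene of calcitonin and of the calcitonin gene-related peptide (chromosome 7, 114631478 to 114636357), fell by 2.96 ± 0.28 per doubling (adjusted p = 2.07e-05, edgeR), from 362 CPM at D3 to 0 at D11 and D20, and its level was 22.7 times that over all barcodes. Tubule genes fell, with 11 of 12 proximal tubule identity genes lower (12 adjusted over the list alone; camera adjusted p = 1.8e-13, adjusted p = 0.324 with an estimated correlation). Among tubule genes, Acy3 fell by 2.24 ± 0.34 and Slc13a1, a sulfate transporter, by 2.10 ± 0.28 (adjusted p = 0.00208 and 0.000798), at 0.423 and 0.447 times their level over all barcodes. Glycolysis genes had 2 rising of 12 (4 adjusted over the list alone; adjusted p = 0.0023, adjusted p = 0.419 with an estimated correlation). Mitochondrially encoded genes had 2 falling of 7 (6 adjusted over the list alone; adjusted p = 3.36e-05, adjusted p = 0.411 with an estimated correlation).

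edgeR called 41 genes rising and 172 falling of 4626 in T cells, and without D3, which has 132 T cells in a single library, 10 in all. The DESeq2 Wald test called 275, 31.6% of them rising against 19.3% with edgeR. The count was 328 without D20 replicate 1, 667 without both D20 libraries, 126 without both D9 libraries, and 98, 8 of them rising, with the libraries of each time point summed. Calca and Slc13a1 kept their calls in each of these fits. Acy3 kept its call in all of them but the fit without D3, where it was not tested.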

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

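All tests in this part were chosen only after the result was seen. In each case below, the slope of a gene list on log2 of the day differed between carcinoma and macrophage barcodes of the same 11 D libraries, by a permutation test of the difference over 16 lists. MHC class I presentation genes differed by 0.4438 per doubling of the day, 0.0887 in carcinoma against -0.355 in macrophages (r = 0.961, p = 2e-05, adjusted p = 0.00032). Without D3 and D20 replicate 2, the 2 libraries farthest from the median on log2 of the day, r was 0.919. Immediate early and dissociation genes differed by 0.3973, 0.133 against -0.264 (r = 0.768, adjusted p = 0.0246, and r = 0.612 without D3 and D20 replicate 2). NF-kB and cytokine genes differed by 0.2785, -0.0178 against -0.296 (r = 0.792, adjusted p = 0.0159, and r = 0.635 without D3 and D20 replicate 2). In the edgeR fits the mean slope of this list was -0.185 in carcinoma (12 genes tested) and -0.267 in macrophages (15 tested). It was negative in both classes there, and the difference was smaller. Tubular injury genes differed by -0.2205, 0.0061 against 0.227 (r = -0.847, adjusted p = 0.00648, and r = -0.859 without D3 and D20 replicate 2). Heat shock genes differed by -0.1969, -0.169 against 0.0282 (r = -0.718, adjusted p = 0.0344). Without D3 and D20 replicate 2 their r was -0.484, so this difference leans on these 2 libraries. These p-values count the libraries of a time point as separate.

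Xist and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d part the D from the NC libraries. In proximal tubule barcodes 13 of 13 libraries lie on the side of their set, as animals of different sex in the 2 sets would give; a mistake in the labels about sex and a planned difference cannot be separated here. Y-linked counts brought by the carcinoma cells are argued against, since the median ratio of carcinoma to macrophage Y-linked CPM was 0.04 (0.0076 to 0.151) over the 11 D libraries. Of 14 tubule genes listed as differing between male and female mice, 64.29% passed the threshold in the male direction, Kap and Akr1c21 (log2 3.81) among them, and 2 passed it the other way, Odc1 (-1.61) and Slc7a12 (1.94). Slco1a1 (0 CPM in NC, 155 in D) and Acsm3 (12.3 and 73.9 CPM) also went in the male direction. They had no usable standard error and could not be called, and Slc22a7 was tested but not called. The median log2 change of the 14, signed by sex, was 2.23, at percentile 100 of 10000 random lists of matched level. Slc7a12 is a leading gene of the unnamed cluster 24, which holds 7.14% and 7.34% of NC barcodes and was not counted as proximal tubule, and Kap was at 0.41 with that cluster counted. How much of the tubule difference between D and NC comes from sex and how much from the tumour cannot be told apart, because every NC library has Xist and every D library has Y-linked counts, and the same holds for the other classes.

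Several genes of the proximal tubule list had falling slopes on the day in macrophage, T cell and carcinoma barcodes (6 of 17, 11 of 12 and 5 of 16 called; adjusted p = 0.337, 0.324 and 0.534 with an estimated correlation). The fall was not steady: the summed list in macrophages was 2443 CPM at D3, 2468 and 708 in the D9 libraries, 532 and 2248 in the D11 libraries, and 218 and 181 at D20. The summed list did not fall in carcinoma barcodes, with 2558 CPM at D3 and 2657 and 2865 at D20, because Gpx3 and Cyp4b1 did not fall there; the other 16 members together were at 1038 CPM at D3, 524 and 165 at D9, 124 and 700.4 at D11, and 9.33 and 6.71 at D20. Log2 levels across the list in carcinoma and macrophage barcodes of the same library correlated with a median of 0.9206 (0.866 to 0.958) over the 18 members, Gpx3 and Cyp4b1 included, which free RNA of tubule cells would give. Over the 16 members without Gpx3 and Cyp4b1 the correlation was only 0.484 and 0.326 in the D20 libraries, so free tubule RNA is not shown there. The 1% of macrophage barcodes with most counts of the list held a median of 13.16% of them (5.86 to 18.6), and 16.5% for the 16 members. Up to D11 that argues against a whole source in about 1% of barcodes that hold a tubule cell beside another cell. If such mixed barcodes are more common the test cannot decide, since each would hold a smaller part of the counts. For the 16 members at D20 the same share was 67.7% and 45.2% of only 68 and 42 counts, which leaves rare mixed barcodes open there too. Free tubule RNA or mixed barcodes may account for the levels of Lrp2 and Slc22a6 in carcinoma and macrophage barcodes up to D11. Free tubule RNA would not account for the level of Gpx3 and Cyp4b1 in carcinoma barcodes, and T cells and biological explanations were not tested.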

How the results depend on the processing

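The fits with a single D coefficient, with libraries summed, without both D20 or both D9 libraries, with clusters 10 and 24 counted, with time point means and with the level limit were chosen only after the result was seen. Of 312 alternatives for shares, 303 kept direction and side of the threshold. Over shares, gene counts and gene lists together, 444 of 521 alternatives stayed within their limits, and of 7747 alternatives for 357 named-gene results 6633 kept the call, 1106 lost it and 8 reversed. Fits without 1 library supplied 3707 of the 6633. With title groups summed, 34 named-gene results kept the call, 192 lost it and 1 reversed. With the libraries of each time point summed, 17 kept it and 113 lost it. The planned results on new RNA were not run, since new and old counts are not separated. Among the comparisons with NC, simulated changes of 1 on the log2 scale were called least often in macrophages (6%), where the NC libraries hold 34 and 31 barcodes. Depth was not tested as the cause. Where leaving out a library left a title group with 1, that library is assumed to vary like the other groups. Unless a fit has fewer libraries or genes, the cause was not tested.

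In D against NC (proximal tubule 3530 genes, macrophage 799, endothelial 1684, T cell 1526), a single D coefficient gave 1056, 368, 269 and 647, and title groups summed 45, 6, 16 and 20. The level limit left 1913 in proximal tubule, 1028 in endothelial and 858 in T cell barcodes. DESeq2 gave 558 in endothelial and 782 in T cell barcodes, and clusters 10 and 24 counted 4925 in macrophages. Leaving out each library gave 2526 to 3555, 333 to 842, 780 to 2021 and 710 to 1922. With the correlation estimated, lists past the threshold went from 11 to 5, 9 to 1, 9 to 0 and 9 to 0.

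In the trend (carcinoma 1028, macrophage 553, proximal tubule 344, T cell 213), the replicate block together with leaving out D3 gave 359, 211, 87 and 6, where leaving out D3 alone gave 609, 351, 195 and 10. Replicate numbers showed no common pairing of the libraries (median correlation -0.0048 over 61 pairs of groups, highest 0.1078). D9 against D11 stood apart, at -0.3581 in carcinoma and -0.3483 in macrophages. There the deviations of replicate 1 at D9 went with those of replicate 2 at D11. Time points summed gave 17, 3, 0 and 98. Without both D20 libraries the counts were 1761, 1137 and 667 in macrophage, proximal tubule and T cell barcodes, and the level limit left 281, 124 and 105. DESeq2 gave 1077 in macrophages and 654 in proximal tubule, where no filter gave 876 and the slope on the day itself 123. In T cells no filter gave 356 (DESeq2 275, 31.6% rising against 19.3%), the slope on the day itself 107, late against early 100, and without both D9 libraries 126. Leaving out each library gave 440 to 1303, 264 to 719, 87 to 629 and 10 to 328. With the correlation estimated, lists went from 5, 8, 8 and 5 to 0 each.

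For shares, the collecting duct principal difference reversed to 0.282 at Leiden resolution 2.0 and ranged from -0.6287 to 0.0461 when each library was left out. The neutrophil trend reversed to -0.0227 at resolution 2.0 and -0.031 on the day itself, and without the D20 pair the fibroblast and collecting duct trends to 0.1163 and 0.1305. T cells (-0.7106) and dendritic cells (-0.7302) passed on the day itself, and macrophages (0.8476) without the D20 pair. Reversed genes were Spp1 in the tubule (0.021, a single D coefficient), Vcam1 (-0.41) and C1qb (-0.59) in macrophages with cluster 10 counted, Igha in T cells (0.11 with title groups summed, -8.53 to 3.79 when each library was left out, the highest without NC replicate 1), Serpina3n in carcinoma (-0.27 without both D20 libraries) and Gatm in the tubule trend (0.18 with the replicate block and D3 left out, -1.66 to 0.22 when each library was left out, the highest, 0.22, without D3 alone).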

Other observations

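All tests in this part were chosen only after the result was seen. Shares of single clusters, and of classes in single libraries, are given here beside the tests of whole classes above. The 2 D9 libraries held 7.63% and 8.43% of barcodes in a macrophage cluster with Cxcl9, Cxcl10 and Ifit2 among its leading genes, and 5.64% and 6.83% in a carcinoma cluster with Iigp1, Igtp and Gbp2. A further carcinoma cluster, with Gbp2, Igtp and Cxcl9 among its leading genes, held 17.1% of D9 replicate 1 and 3.34% of replicate 2, so the D9 carcinoma values below average unlike libraries. The D20 libraries held 8.53% and 8.82% in a macrophage cluster with Arg1 and Mmp12. Fibroblasts were 3.24% and 4.11% of the D7 libraries (95% intervals 2.80 to 3.75 and 3.55 to 4.76). Libraries of the same title group also differed: neutrophils were 3.93% of D9 replicate 1 (3.34 to 4.61) and 11.9% of replicate 2 (11.1 to 12.8), and collecting duct principal cells 0.222% of D11 replicate 1 (0.124 to 0.397) and 5.34% of replicate 2 (4.75 to 5.99). The unnamed cluster with Cx3cr1, Ccl4 and Cd72 went from 8.91% and 9.46% in NC to 3.97% in D3, 7.09% and 7.46% in D5 and at most 1.02% in any library from D7 on. The unnamed cluster with Aadat, Slc7a12 and Slc22a7, and with Havcr1, held 7.14% and 7.34% of NC barcodes and at most 0.02% of any D library.

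The mean log2 level of the interferon list differed between time points in carcinoma and macrophage barcodes. From D3 to D20 in turn it was 5.98, 6.44, 5.85, 6.70, 5.26 and 5.48 in carcinoma, and 6.86, 6.92, 6.31, 6.47, 5.42 and 5.91 in macrophages, with the same sign at each step between neighbouring time points. The steps were not tested one by one. The correlation of the 2 classes over the 6 time points was 0.7814 and did not pass (exact p = 0.0694; rho 0.829, exact p = 0.0583; r = 0.899 without D9 and D11), so a joint movement is not shown. Free macrophage RNA as the source of the list's counts in carcinoma barcodes is argued against, since the carcinoma to macrophage ratio of the list was 14.589 times that of the Y-linked genes in the D5 and D9 libraries (9.30 in the lowest). Depth stays open: the list level in carcinoma barcodes had a Spearman correlation of -0.3364 with median counts per barcode over the 11 D libraries (permutation p = 0.301). A shift shared by a whole group of libraries, from the animals or the collection date, stays open as well, since date and day cannot be told apart.

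The numbers of genes with a slope were set against 100 of the 720 ways to deal the days over the 6 time points, the real one included. In carcinoma barcodes 4 dealings gave as many as the real 1028 genes (highest other 1705) and in T cells 3 gave as many as 213 (highest other 434), each under 5%. These shares were not adjusted over the classes and come from a part of the dealings, so chance order of the days is not excluded there. In macrophages 11 gave as many as 553 (highest other 1474) and in the proximal tubule 9 as many as 344 (highest other 961), so chance order could not be excluded there. The dealing with most genes gave the place of the latest day to D9 in carcinoma and proximal tubule barcodes, to D5 in macrophages and to D11 in T cells.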
